A study of Mus musculus with 6 samples.

How the data were processed

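Bulk RNA-seq was made from foamy and non-foamy macrophages of mouse aortic intima, 3 libraries each. Per the labels' protocols, the adventitia was removed after 8 min of enzymatic digestion and the remaining tissue was digested for 70 min at 37 °C before sorting. Per the same protocols, cDNA was made with the SMARTer Ultra Low kit, amplified for 12 cycles after adapter ligation, and read as single 50-base reads on a HiSeq instrument. The protocols name no molecular identifiers, so reads are not independent molecules, and counting intervals and floors cover counting error only. The submitters' processing notes name STAR 2.0.4b, Subread, featureCounts 1.4.5 and the GRCm38 build. Strandedness and the handling of reads that map to several genes are not given in the sources used here, so values of near-identical gene copies and of overlapping or antisense genes are uncertain.

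Each deposited table lists 41388 Ensembl genes. The deposited counts are whole numbers of reads per gene, not normalized. The deposited CPM values equal the count divided by the total of counts in genes, times a constant. The deposited RPKM values equal that CPM per kilobase of the length in the table. Both were checked on every gene to an absolute tolerance of 1e-06. Tests used the counts. The deposited CPM and RPKM were used only in that check. Symbols came from a table of gene names and were found for 40254 IDs (97.26%). These IDs held at least 99.71% of the counts of each library. Gene classes, such as protein-coding, came from GENCODE M21. Of the genes with a symbol, 76.1% had the same start and end in M21 as in the deposited tables. Coordinates are those of the deposited tables.

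Genes were tested with edgeR 4.0.16 (filterByExpr, TMM, robust quasi-likelihood F-test) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are foamy over non-foamy, and the SE is the size of the log2 fold change divided by the square root of F. Means and SDs are of TMM-normalized CPM over 3 libraries. TMM factors ran from 0.868 to 0.966 in foamy and from 1.035 to 1.186 in non-foamy libraries. The biological coefficient of variation was 0.51. Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted within 17 programme lists and within 15 cell type and quality lists, with an estimated correlation and fry as alternatives; a list needed at least 3 tested members. The lists and tests were fixed before the data were examined, and of 578 distinct list genes 30 stand in more than 1 list.

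The genes named were chosen by a rule fixed at the same time: Itgam, Fcgr1 and Apoe; 13 lipid and inflammatory genes; the 10 largest rises and falls among called genes with an official symbol, groups that do not overlap and a mean of at least 10 CPM; and, in each called list, up to 4 called members in its direction and 2 against it by p, or up to 2 in a list not called. Other members are named where a count was small or a marker was needed, and were chosen after their values were seen. A group with 1 to 3 counts was given a ratio with an exact 95% counting interval.

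Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 10 counts in 3 libraries and a mean of 5 CPM, the replicate number as a block, mitochondrial and ribosomal protein genes left out, a test against a 1.5-fold change, and each library left out. Scaling to total counts only, protein-coding genes only and lists without shared genes were added after the data were examined, as was the 1.5-fold test for single genes. The procedure was tested on simulated data drawn from these libraries' means and sizes with 200 genes changed. It recovered 16.7% of genes changed 2-fold, 39.6% changed 4-fold, 73.5% changed 8-fold and 79.6% changed 16-fold among 11670 tested, and 3.8% of its calls were false. Library measures were compared with scipy 1.17.1. No pair of libraries agreed within sampling noise: chi-square per degree of freedom ran from 54.46 to 173.2 within groups.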

Results

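RNA was measured in 2 macrophage populations sorted from the intimal layer of aortas of ApoE-deficient C57BL/6 mice, a strain that develops atherosclerotic plaques. The series design gives 6 mice on a Western diet for 28 weeks. Foamy macrophages were live CD64+CD11b+ cells with high BODIPY signal, from a dye of neutral lipid, and high side scatter. Non-foamy macrophages were CD64+CD11b+ cells low in both. Each population was sequenced as 3 libraries. Total counts in genes were 24279802, 18592421 and 20641741 in foamy replicates 1 to 3, and 15628627, 16863185 and 24619075 in non-foamy replicates 1 to 3. How the 6 mice were divided among the libraries is not stated, so p-values measure only the spread between these libraries, which may be technical.

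Apoe, the gene disrupted in these mice, was measured in both populations, at 4.96 ± 1.78 CPM (TMM-normalized, mean ± SD, n = 3) in foamy and 4.45 ± 1.66 CPM in non-foamy libraries. No wild-type library was analysed here. The genes of the sorting antibodies were present in all 6 libraries. Fcgr1, which encodes CD64, stood at 232 ± 44.8 CPM in foamy and 182 ± 52.9 CPM in non-foamy libraries and did not pass the test (log2 fold change 0.35, SE 0.24, edgeR adjusted p = 0.50). Itgam, which encodes CD11b, was lower in foamy libraries, at 77.8 ± 7.82 against 142 ± 13.2 CPM (log2 fold change -0.87, SE 0.19, edgeR adjusted p = 0.023). The Itgam call was lost under 8 of 17 alternatives, including without each foamy replicate (log2 fold change -0.80, -0.94 and -0.86 without replicates 1 to 3) and without non-foamy replicate 2 (-0.84) or 3 (-0.81).

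The comparison asked which of the populations carries lipid-handling and which carries inflammatory transcripts. Foamy libraries had more RNA of genes for lysosomal and lipid-storage proteins and of the cholesterol efflux and LXR list. The lipid droplet list was not called without the members it shares with other lists. Of the exporter genes Abca1 and Abcg1, only Abca1 was called, and not without foamy replicate 2 or 3. Non-foamy libraries had more RNA of cytokine and chemokine genes, and with them of monocyte markers (median log2 fold change -2.98, foamy over non-foamy) and of immediate early and heat shock genes (-1.52). Gpnmb, a lysosome-associated glycoprotein, averaged 7879.8 ± 1849.7 CPM in foamy and 755 ± 160.3 CPM in non-foamy libraries (log2 fold change 3.38, SE 0.24, edgeR adjusted p = 3.8e-05). Ctsl, a lysosomal cysteine protease, averaged 5757 ± 615 against 611 ± 30.5 CPM (log2 fold change 3.24, SE 0.18, edgeR adjusted p = 9.0e-06). In the other direction, Il1b, the cytokine interleukin-1 beta, averaged 44.2 ± 13.8 CPM in foamy and 819 ± 179 CPM in non-foamy libraries (log2 fold change -4.21, SE 0.29, edgeR adjusted p = 3.2e-05). On GRCm38, Gpnmb (ENSMUSG00000029816) lies on chromosome 6 from 49036518 to 49058182, Ctsl (ENSMUSG00000021477) on chromosome 13 from 64363214 to 64370306, and Il1b (ENSMUSG00000027398) on chromosome 2 from 129364570 to 129371139. These are whole protein-coding genes, and the counts cover their exons together.

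**Figure D1:**
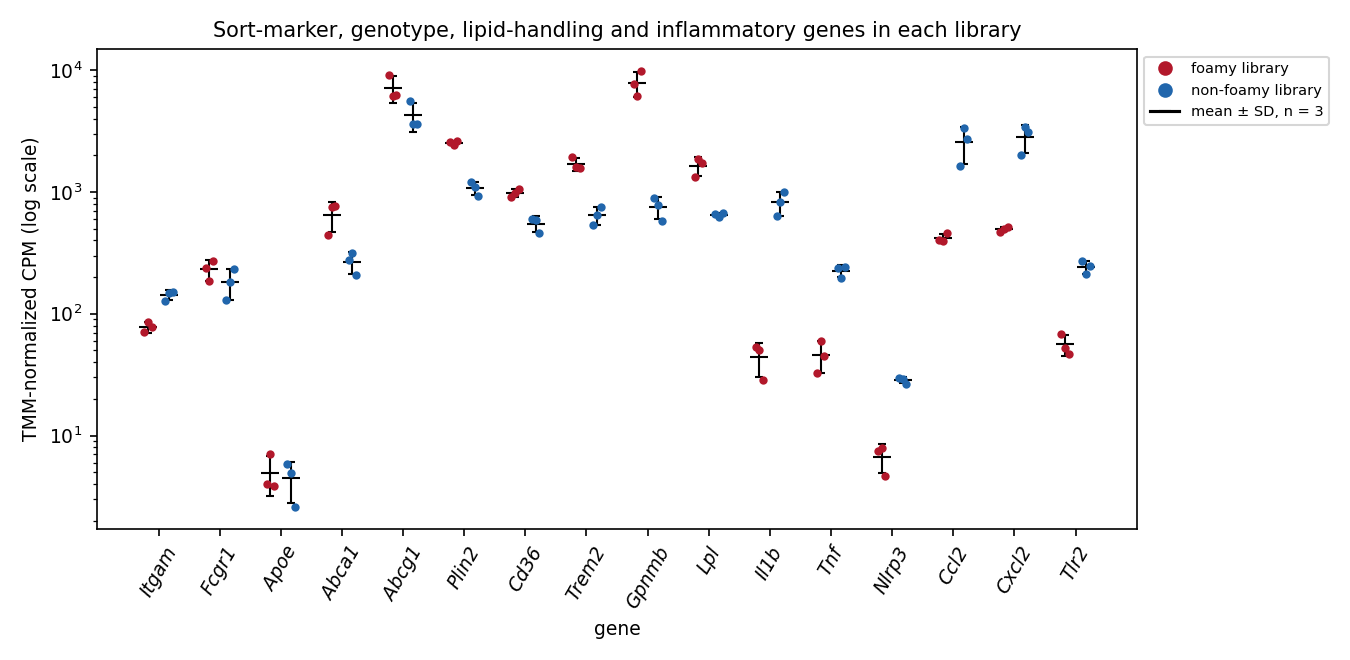
TMM-normalized CPM on a log axis for the genes of the sort markers and genotype and for the lipid and inflammatory genes fixed before the data were examined. Points are libraries (foamy red, non-foamy blue) and black bars are the mean ± SD of 3 libraries. The foamy mean of Il1b was 44.2 CPM and the non-foamy mean 819 CPM.

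Of 11303 genes tested with edgeR, 611 (5.41%) passed an adjusted p of 0.05, with 283 higher and 328 lower in foamy libraries. A change of at least 2-fold was seen in 220 of the higher and 294 of the lower genes. The median log2 fold change was 1.31 among the higher and -2.07 among the lower genes. The 3 foamy values lay entirely above or below the 3 non-foamy values in all 611 called genes. The edgeR test favours such genes, so this is not separate support for the calls. The groups were apart in this way in 25.7% of all tested genes, where chance gives 10%. With total counts as the only scaling, a choice added after the data were examined, 165 genes were higher and 614 lower, and the median of all tested genes moved from -0.04 to -0.31 on the log2 scale. DESeq2 gave 1419 (592 higher, 827 lower), a test against a 1.5-fold change 276 (105 and 171), and a fit without a filter on low counts 888 (457 and 431). The count was 346 (147 higher, 199 lower) without foamy replicate 1, 316 (145 and 171) without foamy replicate 2, 271 (113 and 158) without foamy replicate 3 and 366 (177 and 189) without non-foamy replicate 2.

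Among genes fixed in advance for lipid handling, 6 of 7 rose in foamy libraries. Trem2, a lipid-sensing surface receptor, averaged 1707 ± 211 against 647 ± 111 CPM (log2 fold change 1.4, SE 0.19). Plin2, which coats lipid droplets, averaged 2538 ± 88.8 against 1076 ± 134 CPM (log2 fold change 1.24, SE 0.17). Lpl, lipoprotein lipase, had a log2 fold change of 1.33 (SE 0.18), Abca1, a cholesterol exporter, of 1.29 (SE 0.24), and the scavenger receptor gene Cd36 of 0.84 (SE 0.17). The exporter gene Abcg1 did not pass the test, with 7172 ± 1750.3 against 4252 ± 1151 CPM (log2 fold change 0.75, SE 0.23, edgeR adjusted p = 0.094), but was called without non-foamy replicate 1 (0.996) and without a filter on low counts (0.88). The Abca1 call was lost without foamy replicate 2 (log2 fold change 1.19) or 3 (1.17). The Cd36 call was lost without foamy replicate 2 (0.86), foamy replicate 3 (0.79) or non-foamy replicate 2 (0.90) and with total counts as the only scaling (0.57). Against a 1.5-fold change, neither Abca1 nor Cd36 was called. All 6 fixed inflammatory genes fell in foamy libraries. Besides Il1b, the log2 fold changes were -2.30 for Tnf, -2.09 for the inflammasome sensor gene Nlrp3, -2.61 for Ccl2, -2.51 for Cxcl2 and -2.11 for Tlr2, with edgeR adjusted p between 0.0048 and 8.7e-05. Ccl2, a chemokine for monocytes, averaged 421 ± 32.3 CPM in foamy and 2569.6 ± 873 CPM in non-foamy libraries.

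The 10 largest rises with a mean of at least 10 CPM were Epb41l3, Lbp, Il18bp, Fabp4, Htra1, Epas1, Gpnmb, Apoc1, Ctsl and F7. Epb41l3 averaged 24.6 ± 3.72 against 0.58 ± 0.33 CPM (log2 fold change 5.44, SE 0.56). Fabp4, a fatty acid-binding protein, averaged 145 ± 40.3 against 11.7 ± 1.12 CPM (log2 fold change 3.63, SE 0.27). Il18bp, the secreted antagonist of interleukin-18, averaged 781 ± 301 against 51.9 ± 49.3 CPM. The 10 largest falls were Plac8, Mgl2, Il2ra, Ccr2, Lifr, Cdhr3, Il1r2, F13a1, Il1b and Tnfsf9. Plac8 had 1 count over the 3 foamy libraries and 1485 over the non-foamy libraries, a ratio of 1378 with a 95% counting interval of 247 to 54458. Mgl2, a C-type lectin gene, averaged 0.76 ± 0.52 in foamy and 234 ± 106 CPM in non-foamy libraries. Ccr2, the receptor of Ccl2, averaged 4.37 ± 2.58 against 257 ± 58.2 CPM (log2 fold change -5.87, SE 0.48), and Tnfsf9 averaged 58.4 ± 15.3 against 1035 ± 103 CPM (log2 fold change -4.15, SE 0.23). Without foamy replicate 1, F7 was not called (log2 fold change 2.77), nor was Il1r2 without non-foamy replicate 2 (-4.53). Without foamy replicate 3, the log2 fold change of Il2ra moved from -6.02 to -9.45. Without a filter on low counts, Il18bp (log2 fold change 3.96), Il1r2 (-4.41) and Il2ra (-5.93) were not called, and with the stricter filter Il18bp (3.89) and Il1r2 (-4.58) were not.

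Of 17 programme lists written before the data were examined, camera with a preset inter-gene correlation called 10 higher and 5 lower in foamy libraries. With an estimated correlation, 8 calls held: the lipid-associated macrophage, lysosome, cholesterol efflux, lipid droplet, matrix protease, fatty acid oxidation, inflammatory cytokine and TLR lists. Other splits of the same 6 libraries gave up to 11 called programme lists with the preset correlation. The lipid-associated (Trem2-type) macrophage list had 16 of 23 tested members higher and none lower, with a median log2 fold change of 1.4 (camera adjusted p = 9.5e-56, and adjusted p = 0.0010 with an estimated correlation). The number adjusted over the list alone was 22. The lysosome list had 22 of 37 members higher and none lower, 29 adjusted over the list alone, with a median of 0.90 (adjusted p = 5.0e-34, and 0.021 with an estimated correlation). Its members included Atp6v0d2, a subunit of the proton pump, at 1319 ± 112 against 223 ± 9.50 CPM, the protease Ctsd at 9736 ± 1944 against 2212 ± 209.7 CPM, and Psap at 2159 ± 419 against 692 ± 25.8 CPM. These lists share 6 genes. Without genes that stand in another list, a comparison added after the data were examined, their medians were 0.75 and 0.81, and both calls held. The C1q genes, which mature macrophages express, did not pass the test: C1qb averaged 10138 ± 2548 in foamy and 8715 ± 3234 CPM in non-foamy libraries.

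The cholesterol efflux and LXR list had 9 of 17 members higher and none lower, 10 adjusted over the list alone, with a median of 1.16, or 0.54 without members shared with other lists (camera adjusted p = 3.1e-11, and 0.015 with an estimated correlation). Pltp, a phospholipid transfer protein, averaged 1014 ± 185 against 206 ± 42.0 CPM, and Nr1h3, which encodes LXR alpha, 74.3 ± 13.2 against 25.4 ± 4.45 CPM. The lipid droplet list had 7 of 18 members higher and none lower, with a median of 0.68, or 0.41 with total counts as the only scaling (adjusted p = 9.4e-08, and 0.021 with an estimated correlation). There were 9 higher and 2 lower adjusted over the list alone. Fabp5 averaged 574 ± 12.5 against 69.3 ± 22.3 CPM, and Lipa, the lysosomal acid lipase, 2447 ± 441 against 1101 ± 37.3 CPM. Without the members it shares with other lists, the droplet list had a median of 0.44 and was not called (adjusted p = 0.155, the highest among its alternatives, whose lowest was 1.36e-13). The matrix protease list had 4 of 17 members higher and 1 lower, 9 and 1 adjusted over the list alone, with a median of 0.71, or 0.445 with total counts only (adjusted p = 1.2e-04, and 0.033 with an estimated correlation). Mmp12, macrophage elastase, averaged 15395 ± 262 against 5742 ± 1519.99 CPM and Spp1, osteopontin, 43724 ± 4873 against 15989 ± 2209.98 CPM, while Fn1, fibronectin, was lower (log2 fold change -1.22). The call of Fn1 was lost without foamy replicate 1 (-1.31), 2 (-1.31) or 3 (-1.02) and without non-foamy replicate 1 (-1.02) or 2 (-1.16). That of Mmp14, which was higher (log2 fold change 1.17), was lost without foamy replicate 1 (1.30), 2 (0.90) or 3 (1.31) and without non-foamy replicate 1 (1.03) or 2 (1.18). Without shared members this list had a median of 0.25 and was not called either (adjusted p = 0.1, with alternatives from 1.77e-09 to that value). Sterol biosynthesis genes were not called as a list: 0 of 24 rose and 1 fell, with a median of -0.34 (adjusted p = 0.23), and the member that fell was Insig1, at 29.4 ± 4.83 against 78.0 ± 5.86 CPM. The scavenger receptor list had 6 of 17 members higher, among them Mfge8 and Mertk, and 2 lower, the mannose receptor gene Mrc1 and the haemoglobin scavenger gene Cd163 (7 higher and 4 lower adjusted over the list alone). Its median was 0.40 and its mean -0.12, so that they differed in sign, and the median was 0.099 with total counts only and -0.023 without a filter on low counts. Its camera adjusted p was 0.012, but adjusted p = 0.109 with an estimated correlation, and without non-foamy replicate 1 the list was not called, with a median of 0.60. Its median was about 0.20 without foamy replicate 1 (0.195), foamy replicate 2 (0.199) or non-foamy replicate 2 (0.204), and 0.217 without foamy replicate 3.

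**Figure D2:**
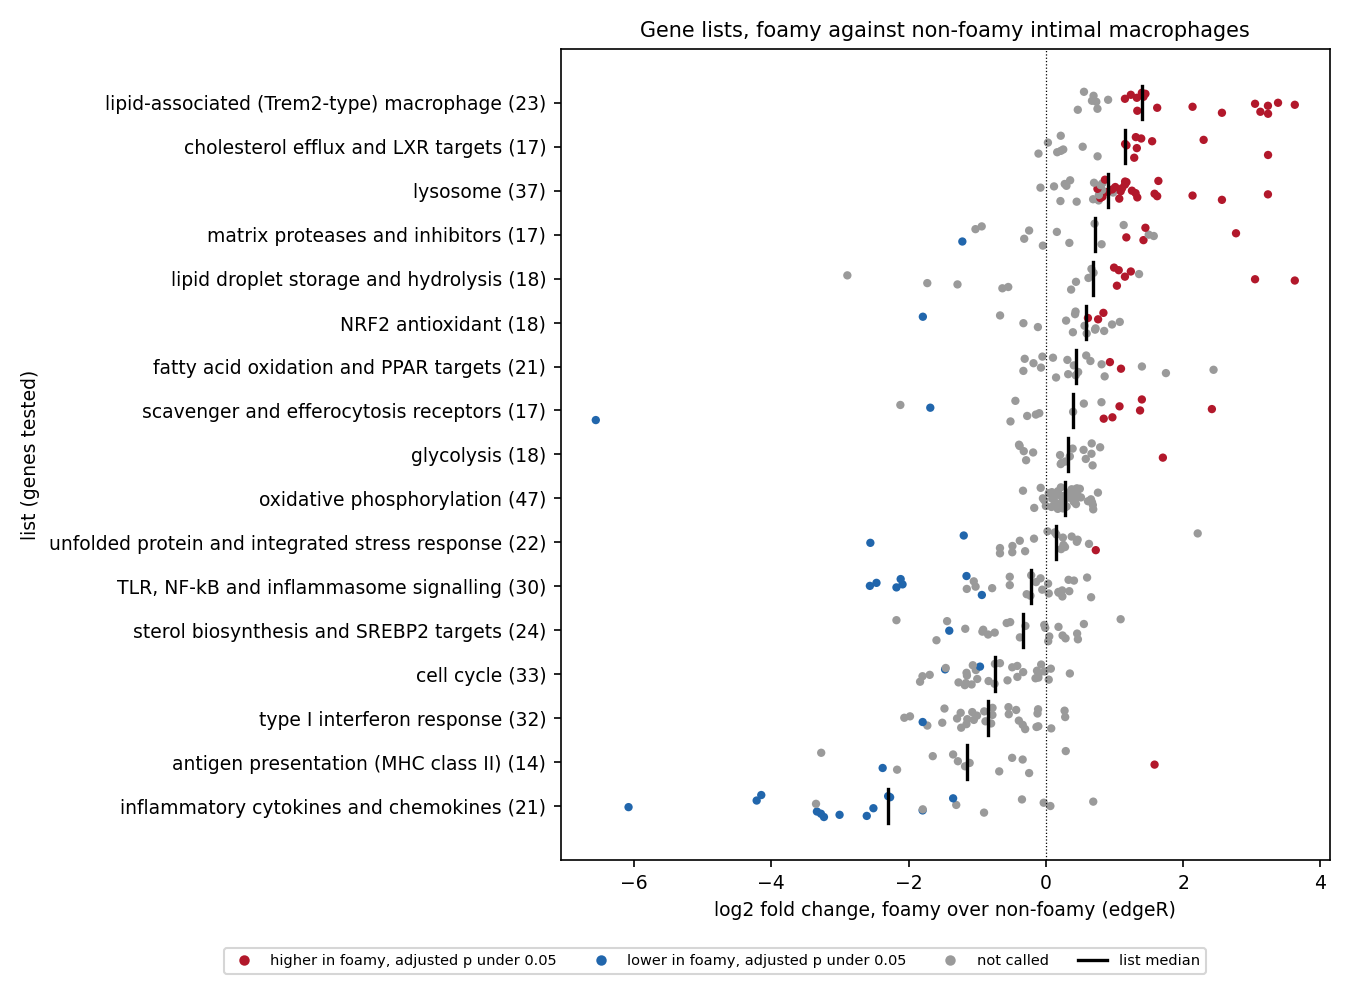
Log2 fold change (foamy over non-foamy, edgeR) of each tested member of the 17 programme lists, 1 point per gene, with the number tested in brackets. Red points were called higher and blue points lower in foamy libraries, grey points were not called, and black bars are list medians, from 1.4 for the lipid-associated list to -2.30 for the inflammatory list.

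The inflammatory cytokine and chemokine list had 13 of 21 members lower in foamy libraries and none higher, with a median log2 fold change of -2.30 (camera adjusted p = 2.3e-37, and adjusted p = 0.023 with an estimated correlation). Adjusted over the list alone, 14 were lower. Besides Tnfsf9, Il1b and Cxcl2, the chemokine gene Ccl3 averaged 186 ± 15.1 against 1497 ± 436 CPM. The TLR, NF-kB and inflammasome list had 7 of 30 members lower and none higher, 7 also adjusted over the list alone, with a median of -0.22 (adjusted p = 5.2e-05, and 0.033 with an estimated correlation). That median was -0.343 without foamy replicate 1 and -0.085 without either foamy replicate 2 or non-foamy replicate 3, and the list stayed called, as it did with total counts only (-0.498) and without a filter on low counts (-0.116). Its member Nfkbia, an inhibitor of NF-kB that NF-kB itself induces, averaged 145 ± 1.97 against 655 ± 97.1 CPM. Its member Nfkbiz averaged 65.0 ± 25.5 against 384 ± 42.5 CPM. Immediate early and heat shock genes, which tissue digestion can induce, were lower in the same foamy libraries: 15 of 19 fell and none rose, 18 adjusted over the list alone, with a median of -1.52 (camera adjusted p = 2.1e-30, and 0.0035 with an estimated correlation). Hspa1a averaged 6.69 ± 2.03 against 59.4 ± 7.22 CPM and Nr4a1 21.1 ± 5.03 against 167 ± 12.5 CPM. Monocyte markers were also lower: 8 of 13 fell and none rose, with a median of -2.98 (camera adjusted p = 1.3e-20, and 0.0035 with an estimated correlation). Adjusted over the list alone, 9 fell and 1 rose. Among them, Cx3cr1 averaged 26.6 ± 1.70 against 155 ± 10.98 CPM.

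Type I interferon, MHC class II and cell cycle lists were also lower by camera, but their calls were lost with an estimated correlation. The interferon list had 1 of 32 members lower, Ifitm3, and 1 adjusted over the list alone, with a median of -0.84, or -0.48 without foamy replicate 2 (camera adjusted p = 5.2e-05, adjusted p = 0.29 with an estimated correlation). The MHC class II list had 1 of 14 members lower and 1 higher, with a median of -1.14, or -0.70 without non-foamy replicate 3 (camera adjusted p = 7.0e-04, adjusted p = 0.29 with an estimated correlation). There were 7 lower and 1 higher adjusted over the list alone. The costimulatory gene Cd86 averaged 101.2 ± 23.7 against 526 ± 35.5 CPM and the protease gene Ctss 31698 ± 2469.6 against 10568 ± 2224 CPM. The cell cycle list had 2 of 33 members lower, Nusap1 and Rrm2, and 5 adjusted over the list alone, with a median of -0.75 (camera adjusted p = 5.2e-05, adjusted p = 0.086 with an estimated correlation). Nusap1 (log2 fold change -1.30 and -1.48) was not called without foamy replicate 2 or 3. Rrm2 was not called without foamy replicate 1 (-1.03), 2 (-0.82) or 3 (-1.01) or non-foamy replicate 2 (-0.995) or 3 (-0.84).

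Fatty acid oxidation and PPAR targets had 2 of 21 members higher, Hadh and Cpt1a, and 6 adjusted over the list alone, with a median of 0.44, which was 0.69 without non-foamy replicate 2 and 0.17 with total counts as the only scaling (camera adjusted p = 3.8e-04, and 0.033 with an estimated correlation). Glycolysis had 1 of 18 members higher, Hk3, and 4 adjusted over the list alone, with a median of 0.32, or 0.04 with total counts only (camera adjusted p = 0.012, adjusted p = 0.16 with an estimated correlation). None of 47 oxidative phosphorylation genes passed the edgeR test, also adjusted over the list alone; the median was 0.28 (camera adjusted p = 4.1e-04, adjusted p = 0.44 with an estimated correlation), and without non-foamy replicate 1 the list was not called, with a median of 0.14. That median was 0.46 without non-foamy replicate 3 and 0.03 with total counts only. The NRF2 list had 3 of 18 members higher, Taldo1, Pgd and Prdx1, and 1 lower, the cystine transporter gene Slc7a11, with a median of 0.58, or 0.31 with total counts only (camera adjusted p = 0.0041, adjusted p = 0.062 with an estimated correlation). There were 7 higher and 2 lower adjusted over the list alone. Leaving out any of the 6 ended the call of Pgd (0.81, 0.72 and 0.78 without foamy replicates 1 to 3, and 0.72, 0.81 and 0.76 without non-foamy replicates 1 to 3) and of Prdx1 (0.63, 0.60, 0.64, 0.55, 0.63 and 0.68 in the same order). Slc7a11 was lost without foamy replicate 1 (-1.67), 2 (-1.93) or 3 (-1.76) or non-foamy replicate 1 (-1.64) or 2 (-1.52), and Taldo1 without foamy replicate 1 (0.80) or 3 (0.81) or non-foamy replicate 2 (0.85). Cpt1a was lost without foamy replicate 2 (1.04) or 3 (0.96) or non-foamy replicate 2 (0.96) or 3 (1.07). Hadh was lost without foamy replicate 1 (0.96), 2 (0.95) or 3 (0.91) or non-foamy replicate 2 (0.84), and Hk3 without foamy replicate 3 (1.55) or non-foamy replicate 2 (1.54). The unfolded protein response list was not called (adjusted p = 0.73), with 1 of 22 members higher, Calr, named after its value was seen, and 2 lower, Herpud1 and Ppp1r15a (not called without foamy replicate 2, at -1.16, or 3, at -1.09); its median of 0.14 and its mean of -0.03 differed in sign, and the median was -0.13 with total counts as the only scaling.

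Markers of other cell types were tested as 15 lists, of which 12 had at least 3 tested members and 5 were called by camera. Several lists had few tested members: 4 of 14 listed genes for T and NK cells, 4 of 13 for dendritic cells and 3 of 10 for B cells. The same held for neutrophils (6 of 14), endothelial cells (4 of 12), fibroblasts (6 of 12) and the osteochondrogenic list (3 of 12). The result of each list rests on its tested members alone. Besides the monocyte and dissociation lists, which held with an estimated correlation, the resident-type macrophage list had 6 of 12 members lower in foamy libraries, with a median of -1.50 (camera adjusted p = 1.8e-04, adjusted p = 0.36 with an estimated correlation). Without members shared with other lists its median was -0.61 and it was not called. There were 6 lower and 1 higher adjusted over the list alone. Cbr2 averaged 7.94 ± 4.23 against 93.2 ± 51.8 CPM, and Lyve1, a hyaluronan receptor, 0.19 ± 0.12 against 17.1 ± 18.9 CPM, a spread between non-foamy libraries as large as their mean. The dendritic cell list had 1 of 4 members lower, Kmo, with 2 counts in foamy and 808 in non-foamy libraries, a ratio of 375 (95% counting interval 103 to 3101), and a list median of -3.94, which was -6.34 without foamy replicate 2 and -1.51 without non-foamy replicate 1 (camera adjusted p = 9.2e-04, adjusted p = 0.068 with an estimated correlation). The T and NK cell list had 3 of 4 members higher, Il7r, Cd4 and Klrb1c, with a median of 2.48, which was 5.02 without non-foamy replicate 2 and -0.094 without a filter on low counts (camera adjusted p = 1.3e-04, adjusted p = 0.054 with an estimated correlation). The dendritic and the T and NK cell lists had the same counts adjusted over the list alone. Klrb1c had 151 counts over the foamy and 3 over the non-foamy libraries, a ratio of non-foamy to foamy of 0.0184 (95% counting interval 0.00376 to 0.0549). Leaving out any of the 6 libraries ended its call (log2 fold change 4.89, 5.43 and 5.92 without foamy replicates 1 to 3, and 6.38, 5.52 and 4.87 without non-foamy replicates 1 to 3). Cd4 was lost without foamy replicate 2 (3.48) or 3 (3.33) or non-foamy replicate 1 (3.13). Il7r averaged 382 ± 53.0 against 139.7 ± 10.97 CPM. For every list whose call was lost with an estimated correlation, that p was the highest among its alternatives, and the lowest ranged from 1.65e-11 for oxidative phosphorylation to 0.000291 for scavenger receptors.

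The remaining lists were not called. The pan-macrophage list had 3 of 14 members higher (Cd68, Mertk and Lyz2) and 4 lower (Itgam, Csf1r, Adgre1 and Cd14), with the same counts adjusted over the list alone and a median of 0.19 (adjusted p = 0.58), which was -0.06 with total counts as the only scaling and -0.03 without non-foamy replicate 1; Lyz2, lysozyme, averaged 34350.3 ± 913 against 14339.6 ± 3123 CPM and Csf1r, the receptor of colony-stimulating factor 1, 132 ± 6.95 against 319.8 ± 70.8 CPM. The neutrophil list had Mmp8 higher and S100a9 and Il1r2 lower among 6 tested (adjusted p = 0.94), with a median of -0.78 against a camera direction upward; without non-foamy replicate 2 the median was 0.41 and neither S100a9 (-6.55) nor Il1r2 (-4.53) was called. The B cell list had Cd22 higher (not called without foamy replicate 3, at 1.89) and Ighm lower among 3 (camera adjusted p of the list = 0.16). Cd22 averaged 52.5 ± 10.5 against 12.5 ± 6.62 CPM. Ighm averaged 89.1 ± 19.4 against 625 ± 63.2 CPM (log2 fold change -2.81, SE 0.21, edgeR adjusted p = 3.8e-05). The call of Ighm was kept under all 16 alternatives that tested it. None of 8 smooth muscle (adjusted p = 0.94) or 4 endothelial genes (adjusted p = 0.59) passed the edgeR test. Serpinf1 was lower among 6 fibroblast genes (adjusted p = 0.13), a list that was called lower without foamy replicate 3 (median -4.25) or non-foamy replicate 2 (-1.70). Serpinf1 itself was not called without foamy replicate 1 (-5.61), 2 (-5.35) or 3 (-5.02) or non-foamy replicate 2 (-5.44) or 3 (-4.26). Spp1 was higher among 3 osteochondrogenic genes (adjusted p = 0.35). In the uncalled lists the counts adjusted over the list alone were the same, except for the neutrophil list with 2 higher and 2 lower. Mast cell, adipocyte and erythroid lists had 0 tested members.

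**Figure D3:**
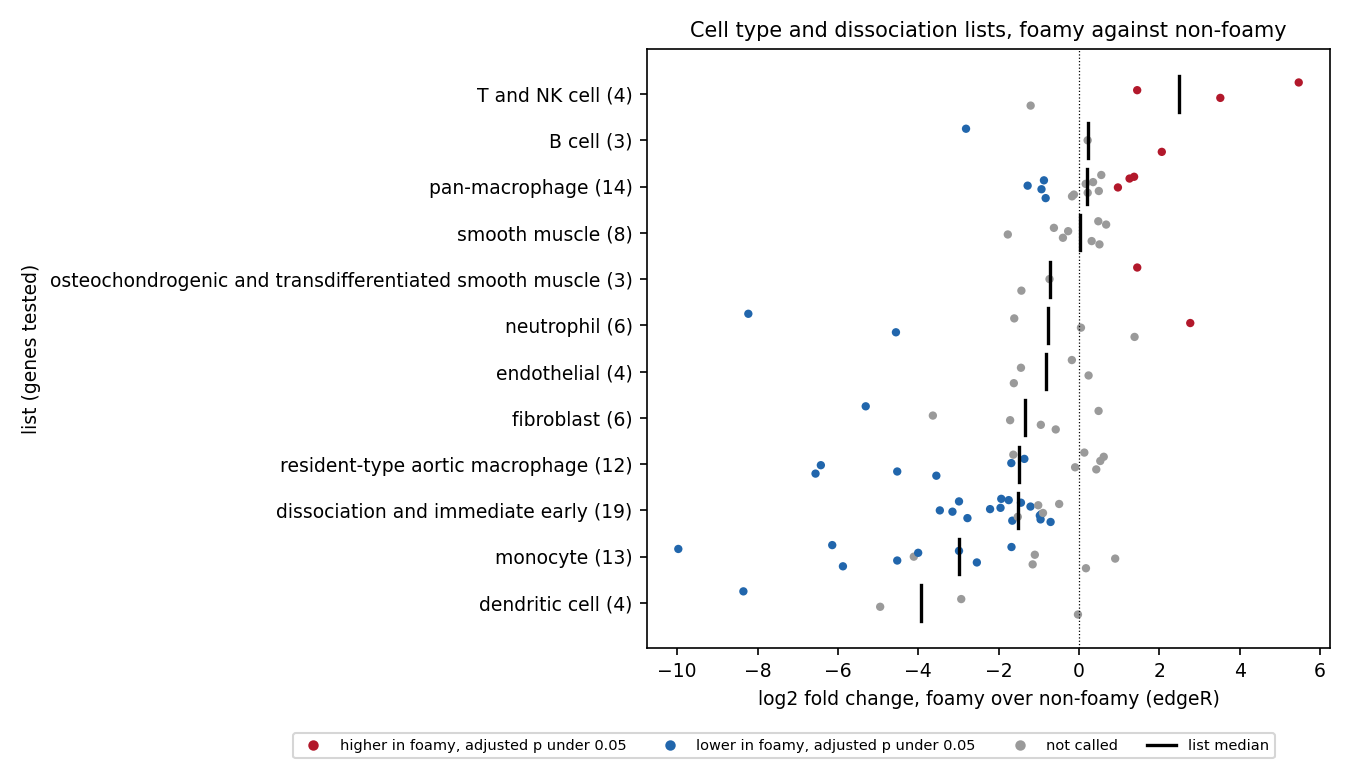
Log2 fold change (foamy over non-foamy, edgeR) of each tested member of the 12 cell type and dissociation lists with at least 3 tested members, 1 point per gene. Red points were called higher and blue points lower in foamy libraries, grey points were not called, and black bars are list medians, which were -1.52 for the dissociation list and -2.98 for the monocyte list.

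Library measures were compared by exact two-sided permutation tests, which with 3 against 3 libraries cannot give a p under 0.1. Non-foamy libraries detected more genes, 21539.7 ± 2798 against 16478 ± 1134 with at least 1 count (exact permutation p = 0.1), with 24701 in non-foamy replicate 1. The difference of 5062 genes was 557.3 with at least 1 CPM and 530.3 with at least 10 counts. The 50 most abundant genes took 45.9 ± 1.12% of foamy and 38.0 ± 1.84% of non-foamy counts (exact permutation p = 0.1). Total counts (exact permutation p = 0.6), the share of mitochondrially encoded genes (1.71 ± 0.32% against 1.93 ± 0.44%, exact permutation p = 0.4) and that of ribosomal protein genes (0.72 ± 0.10% against 0.82 ± 0.18%, exact permutation p = 0.4) overlapped between the groups.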

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

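Scaling to total counts only, protein-coding genes only, lists without shared genes and the 1.5-fold test of single genes were chosen after the data were examined. No called gene among the 611 had the opposite sign under any alternative, and no list that was called under either setting changed its camera direction. Medians of lists that were not called did change sign: the unfolded protein (-0.129), pan-macrophage (-0.06), B cell (-0.054) and smooth muscle (-0.222) lists with total counts only, the B cell (-1.962) and smooth muscle (-0.212) lists without a filter, and the neutrophil list with the stricter filter (1.361). Without 1 library the same held for the pan-macrophage (-0.031) and osteochondrogenic (0.183) lists without non-foamy replicate 1, the neutrophil list without non-foamy replicate 2 (0.413), and the smooth muscle list without foamy replicate 3 (-1.644) or non-foamy replicate 2 (-0.081) or 3 (-0.523). Of 84 named genes that were called, 57 stayed called under every alternative that tested them. Calls were lost with total counts only for Cd36 (0.565), Hadh (0.665), Cpt1a (0.819), Pgd (0.496), Prdx1 (0.349) and Mmp14 (0.931), and with limma-voom for Cd163 (-5.636), Lyve1 (-5.745), S100a9 (-6.619), Serpinf1 (-4.674), Klrb1c (5.116), Slc7a11 (-1.605) and Cpt1a (1.082). Without a filter they were lost for Itgam (-0.777), Rrm2 (-0.86), Il18bp (3.963), Il1r2 (-4.405) and Il2ra (-5.93), and Prdx1 was lost with RLE factors (0.616) and with protein-coding genes only (0.605). Calls numbered 1419 with DESeq2 (592 higher, 827 lower), which held all 611 edgeR calls, and 276 against a 1.5-fold change (105 and 171), where Itgam, Abca1, Cd36, Cd68, Rrm2, Hadh, Cpt1a, Ppp1r15a, Taldo1, Pgd, Prdx1, Slc7a11, Mmp14, Fn1 and Klrb1c were not called. Without a filter, 888 genes were called, 457 higher and 431 lower. With total counts only, 165 were higher and 614 lower. Leaving out 1 library gave 271 to 579 calls, 113 to 285 higher and 158 to 294 lower. The replicate number as a block gave 391 calls, 159 of them higher, and did not call Itgam, Cd36, Rrm2, Hadh, Cpt1a, Taldo1, Pgd, Prdx1, Slc7a11, Mmp14, Klrb1c and Serpinf1; same-numbered libraries did not deviate together (correlations -0.122, -0.033 and -0.048), and no sample correlated best with its own number, which is a hint from the data and does not settle how the libraries were made. Leaving out a library or fitting a block leaves fewer degrees of freedom; the cause of the other differences was not tested.

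With an estimated correlation, 8 programme and 2 cell type lists were called. Medians are unchanged by that choice, and calls were lost for the scavenger (0.398), interferon (-0.838), MHC class II (-1.143), cell cycle (-0.747), oxidative phosphorylation (0.281), glycolysis (0.318), NRF2 (0.58), resident-type (-1.496), dendritic cell (-3.938) and T and NK cell (2.485) lists. With fry, the interferon (-0.838), MHC class II (-1.143), oxidative phosphorylation (0.281) and resident-type (-1.496) lists were not called, while the sterol biosynthesis (-0.337), B cell (0.217) and osteochondrogenic (-0.732) lists were. The camera direction was downward for the B cell list and upward for the osteochondrogenic list, against the sign of their medians. The pan-macrophage list (0.273) was called without a filter, and the fibroblast list with the replicate block (-2.012), without foamy replicate 3 (-4.249) and without non-foamy replicate 2 (-1.698). Without shared genes, the lipid droplet (0.44), matrix protease (0.252) and resident-type (-0.612) lists were not called. Without non-foamy replicate 1, the scavenger (0.595) and oxidative phosphorylation (0.142) lists were not called; over all omissions of 1 library their medians ran from 0.195 to 0.595 and from 0.142 to 0.46. Without a filter on low counts, the medians of the scavenger (-0.023) and T and NK cell (-0.094) lists fell below 0 while the direction of camera did not change. The difference in genes detected was 557.3 at 1 CPM or more and 530.3 at 10 counts or more, against 5062 with any count. Depth limited the smallest groups: Plac8 and S100a9 each had 1 foamy count.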

Other observations

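The tests of the inflammatory and lipid-associated lists below, the search over gene symbols and the count of lists called with an estimated correlation in other splits were chosen after the results were seen. In a search over families of genes that share the leading letters of their symbol, with at least 8 tested members, 8 of 14 Ccl chemokine genes were lower in foamy libraries (Ccl24, Ccl22, Ccl17, Ccl2, Ccl7, Ccl12, Ccl3 and Ccl4) and none was higher, with a median log2 fold change of -2.81 (camera adjusted p = 2.0e-12, adjusted p = 0.83 with an estimated correlation). Of 8 matrix metalloproteinase genes 4 were higher (Mmp14, Mmp12, Mmp8 and Mmp27), with a median of 1.46 (camera adjusted p = 1.5e-05, adjusted p = 0.83 with an estimated correlation). Of 15 Clec lectin genes 6 were lower and 1 was higher, with a median of -0.86 (camera adjusted p = 0.0041, adjusted p = 0.83 with an estimated correlation). The Cxcl, Atp and Anxa families ranked above Clec, with camera adjusted p from 5.9e-05 to 0.0018. No family was called with an estimated correlation, where the lowest adjusted p was 0.83. Ccl2, Ccl3, Ccl4, Ccl7 and Ccl12 also stand in the inflammatory list, and Mmp8, Mmp12 and Mmp14 in the matrix protease list, so these families are not separate evidence. Non-foamy libraries differed among themselves in resident-type markers: Cd163 stood at 1.68, 42.4 and 12.4 CPM and F13a1 at 51.7, 265 and 130.6 CPM in non-foamy replicates 1 to 3.

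The inflammatory list was lower in foamy libraries, by a median of -2.30. Under 4 other settings the median closest to 0 was -2.27. They were RLE factors, upper-quartile factors, total counts only, and mitochondrial and ribosomal protein genes left out, the last of which keeps TMM. Under these settings the median of all tested genes lay between -0.314 and -0.016. Shifts of that size could hardly undo a median of -2.30, so the test says little about normalization. A response to tissue dissociation stays open, because immediate early and heat shock genes were lower in the same libraries, with a median of -1.522; both populations went through the same enzyme digestion protocol, and macrophage activation can induce several of these genes too. Monocytes or cells recently derived from them in the non-foamy gate may also contribute, since the monocyte list had a median of -2.985; its most abundant members in non-foamy libraries were Ccr2 at 257 and Fcgr4 at 178 CPM (333 CPM in foamy libraries, not called), Nr4a1 is shared with the dissociation list and F13a1 with the resident-type list, and the CD64+CD11b+ gate does not remove monocytes that carry CD64. The dendritic cell list was lower too, with a median of -3.938 over 4 tested members, 1 of them called (camera adjusted p = 9.2e-04). Its camera adjusted p was 0.068 with an estimated correlation, and the call was lost. Monocytes are therefore not the only other myeloid cells that may contribute, and the share of each was not tested. A difference between foamy and non-foamy macrophages themselves remains open as well.

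The lipid-associated and lysosome lists were higher in foamy libraries. Dilution of the non-foamy libraries by cells without C1q would raise C1qa, C1qb and C1qc in foamy libraries. The rise would be about the median of the lipid-associated list, 1.4. Their mean log2 fold change was 0.196 (SE 0.179 over 3 genes). That SE is over genes measured in the same libraries and leaves out the spread between libraries. The value lies below 1.4, but whether it does so beyond that spread was not tested. Under the 4 settings named for the inflammatory list, the lowest median of the lipid-associated list was 1.135. For the reason given there, this says little about normalization. A difference between the populations, which were sorted on lipid content, remains a hypothesis. Dilution by cells that express C1q would leave the C1q genes level, so the C1q test cannot exclude it. Markers of resident-type macrophages were lower in foamy libraries, with a median of -1.496 (camera adjusted p = 1.8e-04, adjusted p = 0.36 with an estimated correlation). Whether those cells express C1q was not measured here.

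More genes had at least 1 count in non-foamy libraries, by 5062 on average, against 557.3 at 1 CPM or more and 530.3 at 10 counts or more. Depth is argued against, since after thinning to 15628627 counts the lowest non-foamy library still exceeded the highest foamy library by 603 genes, and so is the larger share of a few abundant genes, since without the 50 most abundant genes and thinned the gap was 318. Background from genomic DNA or unspliced RNA may add to it and stays open: reads on olfactory and vomeronasal receptor genes were 2.967 times as frequent in non-foamy libraries, at 60.1, 24.8 and 11.01 against 8.61, 16.5 and 7.22 CPM, with the most in non-foamy replicate 1, but non-foamy replicate 3 lay below foamy replicate 2. The share of counts in lincRNA genes did not overlap between the groups (0.49 ± 0.06% in foamy and 0.97 ± 0.38% in non-foamy libraries, exact permutation p = 0.1), nor did that in protein-coding genes (98.5 ± 0.21% and 97.7 ± 0.36%, exact permutation p = 0.1), and neither measure separates background from RNA of the cells. The predicted gene Gm10800, singled out after its values were seen, stood at 876, 378 and 237 CPM in non-foamy and 25.7, 153 and 25.3 CPM in foamy libraries.

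Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. Every other split put foamy and non-foamy libraries together on both sides. The difference between the populations then counted as spread within sides, which tends to lower the number of calls. The other splits therefore do not show what libraries without a group difference would give. The real split gave 611 genes and the highest other split 0, with up to 495 genes at an unadjusted p under 0.05 in the other splits against 2119; 1 of the 10 gave as many genes. For programme lists with the preset correlation the real split gave 15 and the highest other 11, and 1 of the 10 gave as many. For cell type and quality lists the real split gave 5 and the highest other 5, and 2 of the 10 gave as many. With an estimated correlation, the real split called 8 programme lists and no other split called any, and it called 2 cell type and quality lists against at most 1.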
